A study of Mus musculus with 3 samples.

How the data were processed

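RNA was sequenced from MIN6 cells, a mouse insulinoma line, in 3 libraries. Per the labels, 1 library came from cells given a negative control siRNA (siNC), 1 from cells given an siRNA against Srsf1 (siSRSF1) and 1 from cells given an siRNA against Srsf2 (siSRSF2). The labels also use the older names of the targets, ASF for SRSF1 and SC35 for SRSF2, and these were used to match the columns to the groups. The labels give Trizol extraction, total RNA as the molecule and a Lifetech library protocol. Whether poly(A) selection or rRNA removal was used, and whether the libraries keep strand, is not given in the sources used here.

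The deposited table holds 1 line per Ensembl gene, with gene coordinates, a length and 2 values per library. The first value is, per the file headers, a read count, which the authors give as whole numbers with no normalisation. The second value is an FPKM computed by the authors, and it was checked to equal the read count divided by the length in the table and by the column total, within 0.00045 percent in every library. Reads were aligned with Bowtie2 2.4.2 to mm10 (GRCm38), per the submitters' processing notes. The counting tool, the annotation release and any filter on reads are not given in the sources used here, nor is how reads that map to more than 1 gene were treated. Counts of near-identical genes, such as the copies of the histone genes, are therefore uncertain. Bowtie2 does not align reads across splice junctions on a genome by itself, and whether a genome or a set of transcripts was the target is not given either. Counts per gene hold no information on exon use, so splicing was not analysed here.

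The table has 21935 lines and 21899 gene symbols. Lines that share a symbol (67 of them) were summed. Of the gene identifiers, 21893 are in GENCODE M21, and 21693 (99.1%) have the same start and end there. Exon number and transcript GC content were taken from that annotation and the GRCm38 sequence, which gave a GC value for 21793 symbols (99.5%). The depth was 12688334 reads for siNC, 14478045 for siSRSF1 and 14682576 for siSRSF2. A level of 3 reads equals 0.239, 0.209 and 0.200 CPM (counts relative to the library total) in these libraries, and was not put in place of 0 reads in any ratio.

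Read counts were scaled between libraries by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, which gave factors of 0.991, 0.990 and 1.020. Scaled levels are given as CPM. Each ratio between a pair of libraries was computed with a prior of 0.5 reads added in proportion to the scaled depth of each. Its 95% interval came from the exact Clopper-Pearson interval of the share of the gene's reads that fell in 1 of the libraries. Each group holds 1 library, so no test between groups was run and no p-value is given. The intervals cover the counting error of these libraries only, and no spread between cultures could be estimated. A gene was compared when it had at least 20 reads in at least 1 library of the pair. It was called higher or lower when its ratio was at least 2-fold and the interval excluded 1.

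Before the data were examined, 29 gene lists, the size rule, the rule for named genes, the comparisons and most alternatives were fixed. The lists cover splicing factors, nonsense-mediated decay, beta-cell identity and secretion, other cell types, the cell cycle, stress responses, translation, metabolism and histones. They hold 827 member entries, and 8 of these had no match in the table (Gas5, Snhg1, Snhg12, Zfas1, Mx1, Mx2, mt-Rnr1 and mt-Rnr2). For each list, the median log2 ratio of its compared members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of expression level. A list was called apart below the 2.5 or above the 97.5 percentile. A percentile of this kind describes these libraries and is not a p-value. Lists needed at least 5 compared members, which left 27. The list of acinar and ductal cells had 3 compared members and the list of fibroblast, endothelial and immune cells had 1, so single genes only are given from these.

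Named genes were Srsf1 and Srsf2, the 8 highest and the 8 lowest ratios per comparison among called genes with at least 100 reads in the higher library, up to 4 members of each list that stood apart, up to 2 of every other list, and a fixed set of beta-cell genes, of which Ins1, Ins2, Pdx1, Mafa and Slc2a2 are reported. Some genes that meet this rule are left out of the text. Predicted genes, clone names, pseudogenes and small RNA genes were left out of the highest and lowest ratios. For targeted genes and some beta-cell genes, the ratio was also ranked among the 500 genes closest in expression. For the overlap of both siRNA libraries, which share the siNC library, reads were drawn 100 times from unchanged groups with counting error alone.

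Transcript GC content was related to the ratios, so a GC-corrected set of log2 ratios was made with lowess (fraction 0.3, 3 iterations, statsmodels 0.14.6). Genes without a GC value kept their uncorrected ratio. The alternatives fixed beforehand were plain library totals, median-of-ratios size factors, no minimum of reads, a minimum of 100 reads, a prior of 5 reads, size rules of 1.5-fold and 3-fold, 20% trimmed means of lists, and FPKM in place of counts. The alternatives chosen after seeing the data were the GC correction, a correction for transcript length, and totals without Ins1 and Ins2 (used without TMM scaling). Leaving out a replicate was not possible with 1 library per group. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

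The steps were tested on simulated data with known changes and counting error alone. The intervals held the simulated ratio for 95.4% of genes in the siSRSF1 against siNC setting, 95.4% in siSRSF2 against siNC and 95.2% in siSRSF1 against siSRSF2. Of 50 genes given a 3-fold change, 100%, 98% and 100% were called in these settings, and all of 50 genes given a 5-fold change were called in each. Of 50 genes given exactly a 2-fold change, 44%, 60% and 48% were called, since the size rule lies at that value. Of 11541, 11569 and 11598 genes compared in these settings, 22, 26 and 16 unchanged genes were called. A list of 30 genes shifted 1.3-fold reached percentile 100.0 in each setting, and 7, 3 and 3 of 100 unshifted lists were called apart.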

Results

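Expression was measured by RNA sequencing in MIN6 cells, a mouse insulinoma line that makes and secretes insulin and is used as a model of the pancreatic beta cell. The design has 3 groups with 1 library each: a negative control siRNA (siNC), an siRNA against Srsf1 (siSRSF1) and an siRNA against Srsf2 (siSRSF2). SRSF1 (also ASF/SF2) and SRSF2 (also SC35) are SR proteins, RNA-binding proteins that promote the splicing of pre-mRNA. The series sets each siRNA library against siNC, and the question is how the transcriptome of an insulin-producing cell differs when either factor is targeted. Totals were 12688334 reads for siNC, 14478045 for siSRSF1 and 14682576 for siSRSF2, and 14584, 15444 and 14238 genes had at least 1 read. Ins2 took the most reads of any gene in each library, with 2.48% in siNC, 2.49% in siSRSF1 and 3.47% in siSRSF2. No difference below has a replicate check, and the intervals given are 95% counting intervals of these libraries.

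Both targeted genes had fewer reads in the library of their own siRNA, by different amounts. Srsf2 (ENSMUSG00000034120, GRCm38 chromosome 11, 116849901 to 116853094) had a CPM of 94.9 in siNC and 32.5 in siSRSF2, a ratio of 0.343 (0.308 to 0.381). Among the 500 genes closest in expression this ratio lay at percentile 0.0. Srsf1 (ENSMUSG00000018379, chromosome 11, 88047373 to 88053755) had a CPM of 323.8 in siNC and 221.3 in siSRSF1, a ratio of 0.683 (0.652 to 0.716), which lay at percentile 0.4 of similarly expressed genes. This was short of the 2-fold size rule, and correction for transcript GC content gave 0.751. Srsf2 in the siSRSF1 library had a ratio of 0.957 to siNC (0.884 to 1.04), an interval that includes 1. Srsf1 in the siSRSF2 library had a ratio of 0.847 (0.811 to 0.884).

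**Figure D1:**
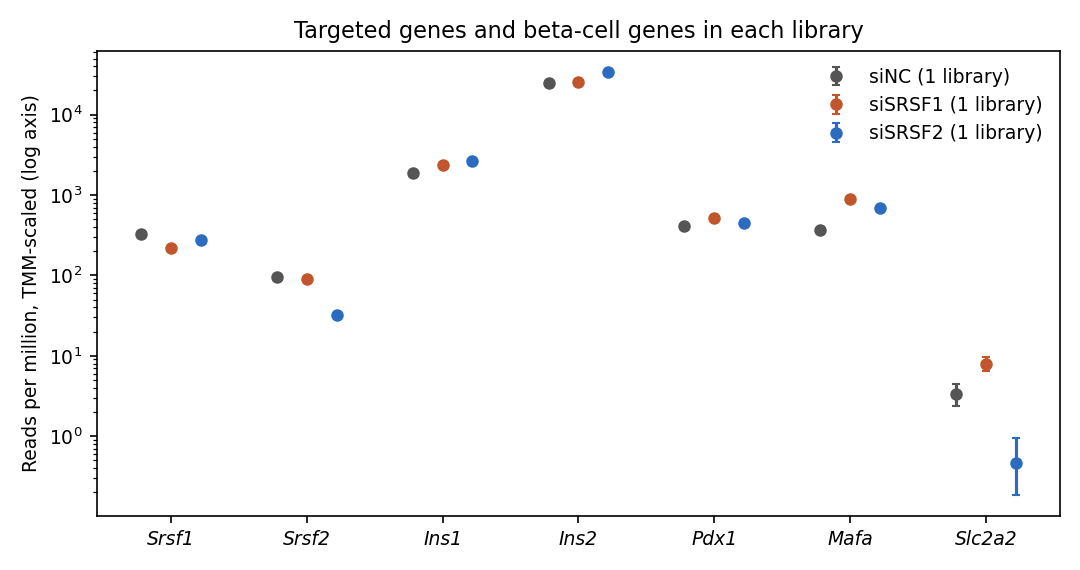
Scaled read counts (CPM, log axis) of the targeted genes and of named beta-cell genes in the siNC, siSRSF1 and siSRSF2 libraries, with 95% Poisson counting intervals and 1 library per group. Srsf2 stands at 32.5 CPM in siSRSF2 against 94.9 in siNC, and Srsf1 at 221.3 in siSRSF1 against 323.8.

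In the siSRSF1 library, genes of replication-dependent histones, cholesterol synthesis and beta-cell function lay above siNC as groups, and ribosomal protein genes lay below. Insm1, a transcription factor of endocrine differentiation, was 2.84-fold higher (2.70 to 3.0). Pcsk1n, which encodes the proSAAS inhibitor of prohormone convertase 1, was 4.64-fold higher (4.40 to 4.90). Hnrnpab, an RNA-binding protein of the hnRNP family, was 4.22-fold higher (3.93 to 4.54). Cckar, the receptor for cholecystokinin, was at 0.267 of siNC (0.203 to 0.343). Of 11602 genes compared, 279 were higher and 139 lower by the size rule.

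Among genes with at least 100 reads in the higher library, predicted genes left out, the highest ratio belonged to Scand1, with 12 reads in siNC and 171 in siSRSF1, a ratio of 12.1 (6.97 to 24.7). GC correction gave 7.73 for Scand1, below Arhgap36 at 11.7 and Slco1a6 at 10.4. Without it, Arhgap36 followed at 11.6 (6.39 to 25.8), from 10 and 138 reads. H3c8, a histone H3 gene, stood at 9.54, Slco1a6, an organic anion transporter, at 9.39, and Stmn4, a stathmin of neurons, at 8.11. C2cd4b was 7.71-fold higher (12 and 109 reads, GC-corrected 4.85), Rab5if 7.39-fold and Mrps34, a mitochondrial ribosomal protein gene, 6.52-fold. The lowest ratio belonged to Kl, which encodes klotho, at 0.243 (0.167 to 0.339). Aass, an enzyme of lysine breakdown, stood at 0.327, Bmf, a pro-apoptotic BH3-only gene, at 0.355 and Eno3, the muscle enolase, at 0.361. Penk and Cartpt, both neuropeptide precursors, stood at 0.367 and 0.392, and Tcim at 0.395.

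Among beta-cell genes, the list of function and glucose sensing had a median log2 ratio of 0.20 over 32 members, at percentile 99.96 of random lists (GC-corrected 0.14, percentile 99.35). Of these, 1 was called higher, 0 were called lower and 22 lay above 0. The called gene was Slc2a2, the GLUT2 glucose transporter, with 42 reads in siNC and 114 in siSRSF1, a ratio of 2.37 (1.66 to 3.48). The cation channel gene Trpm5 had a ratio of 1.88. The prolactin receptor gene Prlr had a ratio of 0.551 in the same list. Among 22 beta-cell transcription factors, Insm1 and Mafa were called higher, and the median of 0.06 was not apart (percentile 77.36). Mafa, an activator of insulin transcription, was 2.47-fold higher (2.38 to 2.55), and GC correction gave 1.79 and ended the call. Pdx1 had a ratio of 1.26, Ins1 of 1.26 (1.24 to 1.28) and Ins2 of 1.01.

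Exocytosis genes had a median of 0.12 at percentile 97.52 (31 members, 1 lower), which GC correction moved to percentile 92.74, and no minimum of reads, length correction and a trimmed mean also ended the call. In that list, Cplx1, a complexin, stood at 0.406 (0.227 to 0.685), Rab37 at 1.60 and Syt11 at 1.44. Prohormone processing and granule genes had a median of -0.08 (25 members, 1 higher, percentile 8.23), and GC and length correction placed them apart at percentiles 1.02 and 1.09. Pcsk1n was the called member, and the signal peptidase subunit Spcs3 stood at 0.543. Disallowed genes, which are kept low in beta cells, had a median of -0.33 over 14 members at percentile 0.09 (mean 0.04). The members were mixed, with 9 below 0 and 5 above, and 1 was called higher and none lower. In this list Tgm2 stood at 0.594, Igfbp4 at 0.719 and Hk1 at 0.730. Among 7 genes of other islet cells, Cck was called higher and Tph1, the serotonin-making enzyme, lower (0.460), with a median of 0.18 at percentile 86.91. Cck had 36228 reads in siNC and 83276 in siSRSF1, a ratio of 2.02 that GC correction put at 1.83, below the size rule.

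Few genes of other cell types had enough reads. The ductal keratin Krt7 was 2.05-fold higher (GC-corrected 2.0, which ended the call), Spp1 stood at 0.554, and the macrophage marker Cd68 was 3.61-fold higher, from 56 and 232 reads.

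Replication-dependent histone genes had a median log2 ratio of 0.96 over 13 compared members, at percentile 99.99. Of these, 13 lay above 0 and 5 were called higher. H4c9 had 150 reads in siNC and 624 in siSRSF1, a ratio of 3.64 (3.05 to 4.39). The ratios of H1f1 (14.1, interval 3.28 to 831), H3c3 (9.08, 2.73 to 95.5) and H3c15 (8.23, 2.93 to 47.8) rest on 1, 2 and 3 reads in siNC. These 3 called genes passed the minimum of reads only through siSRSF1, so they had to lie above 0. The median and the count above 0 are therefore partly set by that minimum. Without a minimum, the summed reads of all 28 members were 2018 in siNC and 4657 in siSRSF1, a ratio of 2.02 (1.92 to 2.13). Cholesterol and fatty acid synthesis genes had a median of 0.23 over 30 members (percentile 99.99), with 26 above 0 and 1 called, Fdps, at 2.78 (2.05 to 3.85). Insig1, which restrains sterol synthesis, stood at 1.57. Nuclear genes of oxidative phosphorylation had a median of 0.16 over 35 members (percentile 99.91), which length correction moved to percentile 77.70. Atp5o (14 and 51 reads, 3.12) and Cox5a (2.34) were called higher in that list, and Uqcrfs1 stood at 1.90. G1/S genes had a median of 0.14 over 35 members (percentile 99.11) with none called, and Gins1 stood at 1.46, Uhrf1 at 1.42 and Gins2 at 1.36.

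Ribosomal protein genes lay below siNC, with a median of -0.19 over 38 members at percentile 0.00, 31 of them below 0 and none called. Rpl37 stood at 0.670, Rps27 at 0.686 and Rps4x at 0.687, while Rps2 stood at 1.41. Mitochondrially encoded genes had a median of -0.14 over 12 members (percentile 6.31), which GC correction moved to 0.03 and length correction to -0.26 at percentile 0.46, apart. Glycolysis genes had a median of 0.06 (21 members, percentile 77.33), with Pfkfb3 at 0.598 and Slc2a1 at 1.38. The median of insulin and growth factor signalling was 0.11 (31 members, percentile 97.16, apart at 97.63 after length correction), and Igf2 was called higher there at 2.4 (2.19 to 2.63).

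No splicing factor list stood apart in siSRSF1. SR and SR-related genes, the target included, had a median of -0.02 over 27 members (percentile 36.04) with none called, and Srsf9 stood at 1.58. Other splicing regulators had a median of -0.03 over 38 members (percentile 26.14), with Hnrnpab and Esrp2 called higher. Esrp2 had 7 and 22 reads, a ratio of 2.65 (1.14 to 7.64). Core spliceosome genes had a median of 0.05 over 39 members (percentile 85.44), with Sf3b5 at 1.56 and Snrpd3 at 1.49. Genes of the nonsense-mediated decay machinery had a median of 0.05 (16 members, percentile 72.06, Rbm8a at 1.32), and transcripts known to respond to that decay or to stress had 0.02 (12 members, percentile 57.23, Atf3 at 1.81).

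Stress and cell-cycle lists other than G1/S were not apart in the siSRSF1 library. G2/M genes had a median of 0.01 (36 members, percentile 60.54) and heat shock and proteasome genes 0.07 (22 members, percentile 84.98). The unfolded protein and integrated stress response had -0.06 (32 members, percentile 10.27), DNA damage response genes -0.01 (28 members, percentile 38.39) and interferon genes -0.05 (15 members, percentile 33.55). Of 26 p53 targets, Phlda3 (4.02) and Bbc3 (2.19, GC-corrected 1.57) were called higher, with a median of 0.02 at percentile 58.89. Apoptosis regulators had a median of -0.14 (26 members, percentile 3.54), with Bmf lower and Bbc3 higher. Immediate early genes had a median of 0.02 (26 members, percentile 57.99), with Maff (2.31) and Jund higher and Nr4a3, an orphan nuclear receptor gene, lower at 0.324. Oasl1 was the called interferon gene, at 2.59.

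The ratios followed transcript GC content, with a Spearman rho of 0.338 across genes, which are not independent replicates. The median log2 ratio went from -0.15 in the tenth of genes with the lowest GC content to 0.23 in the highest. After GC correction 232 genes were higher and 138 lower, and 221 and 116 of the genes called before stayed in the same call.

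**Figure D2:**
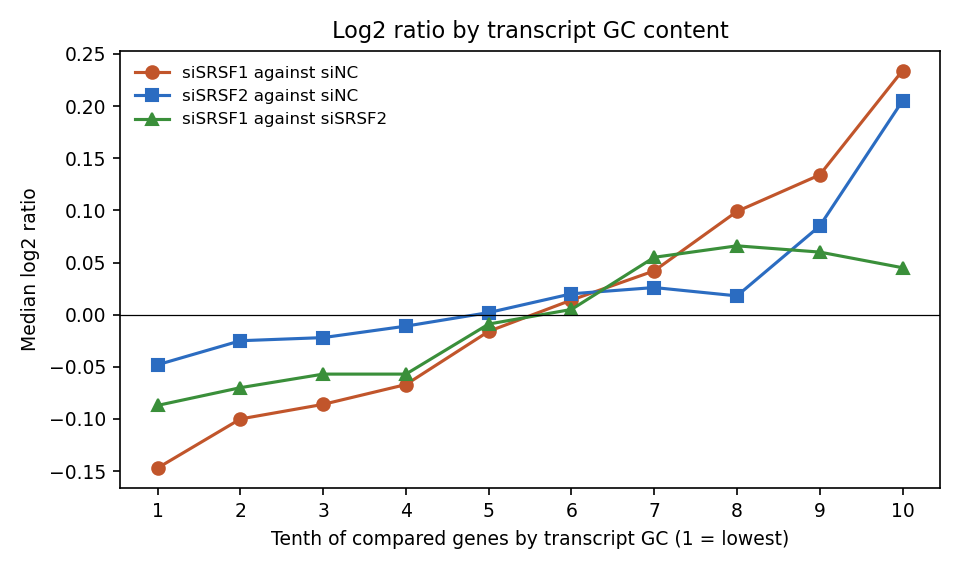
Median log2 ratio of scaled reads (vertical axis) of compared genes in 10 equal groups ordered by transcript GC content (horizontal axis, 1 is the lowest), for siSRSF1 and siSRSF2 against siNC and for siSRSF1 against siSRSF2. The siSRSF1 line runs from -0.15 to 0.23, and the siSRSF2 line from -0.05 to 0.21.

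In the siSRSF2 library, genes of cholesterol synthesis, the heat shock response, G2/M and ribosomal proteins lay below siNC as groups, and transcripts known to respond to nonsense-mediated decay or stress lay above. Hspa8, the constitutive HSC70 chaperone, had 33782 reads in siNC and 16205 in siSRSF2, a ratio of 0.403 (0.395 to 0.410). Hmgcs1, a cholesterol synthesis enzyme, stood at 0.398 (0.360 to 0.438). Trib3, a pseudokinase induced in the integrated stress response, was 2.47-fold higher (2.31 to 2.65). Slc2a2 had 42 reads in siNC and 7 in siSRSF2, a ratio of 0.149 (0.0530 to 0.314). Of 11611 genes compared, 291 were higher and 121 lower by the size rule.

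By the same rule Scand1 again had the highest ratio, 10.8 (6.19 to 22.0, GC-corrected 6.93), followed by C2cd4b at 8.06 (12 and 119 reads, GC-corrected 5.09). Nrtn, which encodes neurturin, stood at 7.54 (5.09 to 12.0, GC-corrected 4.03), the nuclear receptor gene Nr2f6 at 7.12 and Pcsk1n at 6.67 (6.33 to 7.03). Fgfbp3 stood at 6.32, Cebpb, a bZIP transcription factor, at 5.55 and Rab5if at 5.43. The lowest ratio was that of Bhlha15, which encodes the secretory cell transcription factor MIST1, with 512 and 85 reads, a ratio of 0.140 (0.109 to 0.176). Myo15b stood at 0.277, Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, at 0.311, and Tax1bp3 at 0.326. Lars2, the mitochondrial leucyl-tRNA synthetase, stood at 0.342, although whether reads from repeats or rRNA add to its count was not settled. Gmppb, an enzyme of GDP-mannose synthesis, stood at 0.355 and Cckar at 0.359.

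Cholesterol and fatty acid synthesis genes had a median log2 ratio of -0.34 over 30 members (percentile 0.00), with 26 below 0 and 2 called lower, Hmgcs1 and Msmo1 (0.421). Mvd, another enzyme of the pathway, stood at 0.612. Heat shock and proteasome genes had a median of -0.37 over 21 members (percentile 0.00), with 19 below 0 and Hspa8 and Hspa1b (0.417) called lower. Hsph1 stood at 0.502 and Hspa1a at 0.510, and median-of-ratios scaling (0.497) or length correction (0.496) for Hsph1 and GC correction (0.458) for Hspa1a put them past the size rule. G2/M genes had a median of -0.43 over 36 members (percentile 0.00), with 35 below 0 and none called. The mitotic kinesin Kif20a stood at 0.601, Plk1, a mitotic kinase, at 0.611, Cks2 at 0.632 and Cdc20, an activator of the anaphase-promoting complex, at 0.654. G1/S genes had a median of 0.07 (35 members, percentile 93.97), with Fen1 at 0.575. GC correction left the first 3 of these lists at percentile 0.00.

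Transcripts known to respond to nonsense-mediated decay or stress had a median of 0.37 over 12 members (percentile 99.96), with Atf3 (2.57) and Trib3 called higher and 10 above 0. Sesn2 stood at 1.75 and Chac1, a glutathione-degrading enzyme, at 1.59. Gas5, Snhg1, Snhg12 and Zfas1 of this list had no match in the table. Atf3, Trib3, Sesn2 and Chac1 also belong to the list of the unfolded protein and integrated stress response. The median of this list therefore cannot separate an effect on decay from a stress response. The list of the unfolded protein and integrated stress response had a median of -0.26 over 32 members (percentile 0.00), with Atf3 and Trib3 higher and 2 members lower. The lower genes were Manf (0.480, 0.448 to 0.513) and Dnajb9 (0.482, 0.454 to 0.511), both induced by unfolded proteins in the endoplasmic reticulum. Totals without the insulin genes gave 0.501 for Dnajb9, just outside the size rule. Immediate early genes had a median of 0.36 over 26 members (percentile 99.99), with Maff (2.36), Ier5 (2.05) and Atf3 called higher. Jun stood at 1.97 (2.03 and past the size rule with plain totals). The title of that list also names stress kinases, but it holds no kinase gene.

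Beta-cell transcription factors had a median of 0.17 over 22 members (percentile 98.74), which GC correction moved to 0.07 and percentile 89.15. Foxa1 (13 and 45 reads, 2.84), Insm1 (2.45) and Nkx6-1 (2.10, GC-corrected 1.88) were called higher and Bhlha15 lower. Mafa had a ratio of 1.90 and Pdx1 of 1.10. Genes of beta-cell function and glucose sensing had a median of 0.05 (32 members, percentile 92.30, apart at 97.60 with a trimmed mean), with Slc2a2 lower and the zinc transporter Slc30a8 at 0.527. Ins1 had a ratio of 1.43 (1.41 to 1.46) and Ins2 of 1.36 (1.35 to 1.36), at percentiles 95.6 and 93.4 of similarly expressed genes. Prohormone processing and granule genes had a median of -0.28 over 25 members (percentile 0.13), with 19 below 0. In that list Sec61a1, a subunit of the protein translocation channel, stood at 0.586 and Ssr1 at 0.598, while Pcsk1n was the 1 called member. Exocytosis genes had a median of -0.02 (31 members, percentile 50.33), with Rab3d at 0.586. Disallowed genes had a median of -0.19 (13 members, percentile 2.19), but GC correction and no minimum of reads ended the call, and a trimmed mean gave 0.03. Lmo4 stood at 1.964 (2.02 with plain totals) and Nfib at 1.78 in that list. Among 6 genes of other islet cells, Cck was called higher (2.10, GC-corrected 1.98), Sst stood at 0.638, and the median was -0.17 (percentile 12.38). The keratin gene Krt8 was called lower at 0.469, Krt7 stood at 0.932 and Cd68 at 0.826.

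Ribosomal protein genes had a median of -0.34 over 38 members (percentile 0.00), with 34 below 0 and none called, among them Rps6 at 0.596 and Rpl15 at 0.676. Mitochondrially encoded genes had a median of -0.36 over 12 members (percentile 0.25), with 11 below 0. The members mt-Nd3 (27 and 13 reads, 0.414) and mt-Nd4l (0.459) were called lower, and mt-Nd1, with 43519 and 35508 reads, stood at 0.685. A prior of 5 reads gave 0.527 for mt-Nd4l and ended its call. Nuclear genes of oxidative phosphorylation had a median of 0.01 (35 members, percentile 70.38), with Atp5o called higher at 2.53, from 14 and 43 reads. Glycolysis genes had a median of -0.24 over 21 members (percentile 0.34), with Pfkfb3, which makes the activator of phosphofructokinase, called lower at 0.478 and 20 below 0. Ldha stood at 0.603 and Pgk1 at 0.605. Insulin and growth factor signalling had a median of 0.06 (30 members, percentile 93.01), with Eif4ebp1, a repressor of translation initiation, called higher at 2.30.

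Of 27 SR and SR-related genes, 21 lay below 0, with a median of -0.21 at percentile 0.50. Srsf2 was the 1 called member, Srsf11 stood at 0.715, Srsf3 at 0.739 and Srsf9 at 1.67. Core spliceosome genes had a median of -0.14 over 39 members (percentile 0.90), and a trimmed mean moved it to percentile 7.21. Prpf38a stood at 0.707, Sf3a1 at 0.719 and U2af1 at 0.725, while Sf3b4 stood at 1.38. Other splicing regulators had a median of -0.02 (37 members, percentile 64.42), with Hnrnpab higher at 2.79 and the neuronal splicing factor Nova2 at 1.65. The decay machinery had a median of 0.07 (16 members, percentile 81.29), with Rbm8a at 0.742 and Smg9 at 1.33.

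The remaining lists were not apart in the siSRSF2 library. The p53 targets had a median of -0.03 (25 members, percentile 23.91), with Bbc3, which encodes PUMA, higher at 2.83 and Plk2 lower at 0.376. DNA damage response genes had -0.11 (28 members, percentile 3.71, apart at 1.5 with a trimmed mean), with Prkdc at 0.707. Apoptosis regulators had -0.03 (25 members, percentile 18.41), with Bmf at 1.59. Interferon genes had 0.12 (16 members, percentile 60.70), with Usp18 at 1.86. Histone genes had -0.21 over 8 members (percentile 5.55), with H4c9 called higher at 2.83. The siSRSF1 median was taken over 13 members, so these medians do not compare the same genes. The histone median turned to 0.54 both without a minimum of reads (percentile 98.80) and with a minimum of 100 reads (percentile 98.33), and was then apart.

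The ratios followed transcript GC content here too, with a Spearman rho of 0.168 across genes. After GC correction 250 genes were higher and 139 lower, and 246 and 121 of the genes called before stayed in the same call.

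**Figure D3:**
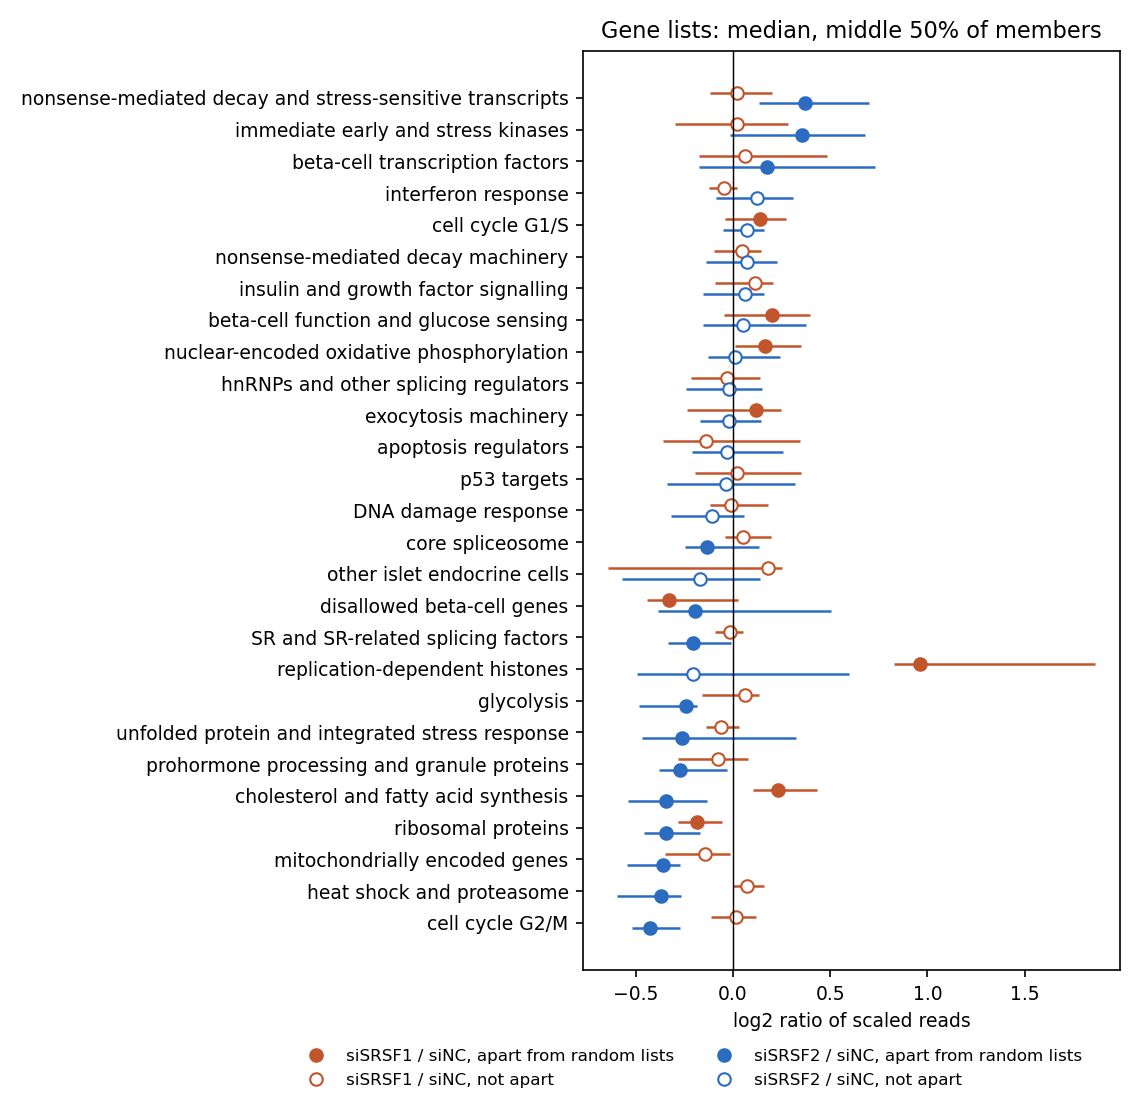
Median log2 ratio of scaled reads for each gene list (points) with the middle 50% of its members (lines), for siSRSF1 (orange) and siSRSF2 (blue) against siNC, with filled points for lists apart from random lists. Replication-dependent histones stand at 0.96 in siSRSF1, and G2/M genes at -0.43 in siSRSF2.

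The siRNA libraries were also set against each other, a comparison without the shared control. Cholesterol synthesis, heat shock, glycolysis, G2/M and histone genes were higher in siSRSF1 than in siSRSF2 as groups, and decay- or stress-responsive transcripts and immediate early genes were lower. Slc2a2, with 114 reads in siSRSF1 and 7 in siSRSF2, had a ratio of 15.9 (8.0 to 43.3). Hspa8 had a ratio of 2.47 (2.42 to 2.51) and Trib3 of 0.464 (0.436 to 0.494). Of 11705 genes compared, 230 were higher in siSRSF1 and 281 lower.

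By the same rule the highest ratio was that of Arhgap36, at 19.3 (9.73 to 52.2). Stmn4 stood at 8.96, Lars2 at 6.17, Lyve1, a hyaluronan receptor gene, at 6.06, Bhlha15 at 5.48, Slco1a6 at 5.19 and Atg9b at 5.12. The lowest was that of Pcdh20, a protocadherin, at 0.162 (0.0906 to 0.261). Bmf stood at 0.222 (0.159 to 0.301), Lrrc17 at 0.255, Tcim at 0.279 and the chromatin organiser gene Satb1 at 0.280. Nr4a3 stood at 0.286, Fat4 at 0.304 and Tcp11l2 at 0.307. Srsf2 had a ratio of 2.79 and Srsf1 of 0.807.

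Each of the 30 cholesterol and fatty acid synthesis genes lay above 0, with a median of 0.56 and 4 called higher: Fdps (3.94), Msmo1 (2.63), Hmgcs1 (2.56) and Insig1 (2.28). Heat shock and proteasome genes had a median of 0.43 over 22 members, with Hspa1b (2.91), Hspa1a (2.57) and Hspa8 called higher. G2/M genes had a median of 0.41, with 35 of 36 above 0, among them Cdc20 at 1.95, Plk1 at 1.74 and Ube2c at 1.69. Glycolysis genes had a median of 0.38 over 21 members, with Slc2a1 at 1.57, Ldha at 1.46 and Gapdh at 1.44. These 4 lists and the histones were at percentile 100. Histone genes had a median of 0.98 over 13 members, with 5 called higher, among them H2bc4 (158 reads in siSRSF2 and 608 in siSRSF1, 4.01) and H1f5 (2.49). Here too H1f1, H3c3 and H3c15 passed the minimum of reads only through siSRSF1. Nuclear genes of oxidative phosphorylation had a median of 0.19 (35 members, percentile 99.62), which length correction moved to percentile 74.74, with Ndufb5 at 1.52. Mitochondrially encoded genes had a median of 0.32 (11 members, percentile 98.39), with mt-Co2 at 1.36 and mt-Co1 at 1.27. A minimum of 100 reads, length correction and a trimmed mean each ended that call.

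Decay- or stress-responsive transcripts had a median of -0.45 over 12 members (percentile 0.00), with Trib3 called lower, Chac1 at 0.539, Sesn2 at 0.572 and Ddit3 at 0.612. Immediate early genes had a median of -0.46 over 26 members (percentile 0.00), with Nr4a3, Dusp6 (0.479) and Npas4 (0.485) called lower. Of the other lists, 18 were not apart. A trimmed mean placed core spliceosome and DNA damage response genes apart (percentiles 99.42 and 98.52), and length correction did so for SR and G1/S genes (97.97 and 97.75). Beta-cell function genes stood apart with no minimum of reads (97.89), and disallowed genes with a minimum of 100 reads (2.03). Called genes in the lists that were not apart, or held too few members, included Krt8 (3.33), Krt7 (2.20), Cd68 (4.38), Phlda3 (2.72), Bok (2.21), Oasl1 (2.37) and Grb10 (3.93), which were higher in siSRSF1. Sdf2l1, an endoplasmic reticulum stress gene, stood at 2.13, and length correction gave 1.98 and ended its call. Lmo4 (0.380), Ddx58 (0.337), Foxa1 (0.493) and Nova2 (0.496) were lower, although a prior of 5 reads gave 0.540 for Foxa1 and 0.504 for Nova2 and ended both calls. Ins1 had a ratio of 0.878, Ins2 of 0.742, Mafa of 1.3 and Pdx1 of 1.15.

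Among 11457 genes compared in both siRNA libraries against siNC, 100 were higher in both and 25 lower in both. Genes higher in both included Scand1, C2cd4b, Rab5if, Mrps34, Nrtn, Pcsk1n, Hnrnpab, Insm1, Cck and H4c9, and genes lower in both included Cckar. With 209 and 222 genes higher, independent calls would share 4.05, and simulated unchanged groups shared a median of 2 and at most 7. A gene short of the minimum of reads in siNC entered this set only when both siRNA libraries reached it. That left out some genes higher in 1 siRNA library alone, since 279 and 291 genes were called higher in the separate comparisons. The value of 4.05 is therefore no fair baseline for the higher genes. With 139 and 121 genes lower, independent calls would share 1.47, and simulated groups shared a median of 1 and at most 4. Opposite calls were made for 6 genes, which were identified after their values were seen: Slc2a2, Lars2 and the predicted genes 4930562C15Rik and Gm10800 were higher in siSRSF1 and lower in siSRSF2, and Pcdh20 and Fam13c the reverse. Reads from repeats or rRNA were not excluded for Lars2 and Gm10800. The log2 ratios had a Pearson r of 0.471 and a Spearman rho of 0.382 across genes, against medians of 0.576 and 0.501 in simulated data. Their covariance was 0.0818, against 0.0139 in simulated data. Part of the overlap may come from the shared control library, which the design cannot split from a difference common to both siRNAs. Of the genes with a GC value, 74 of 98 higher and 23 of 25 lower stayed in the same call after GC correction. Calls made afresh gave 77 genes higher and 29 lower in both, including genes without a GC value, which were not corrected.

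**Figure D4:**
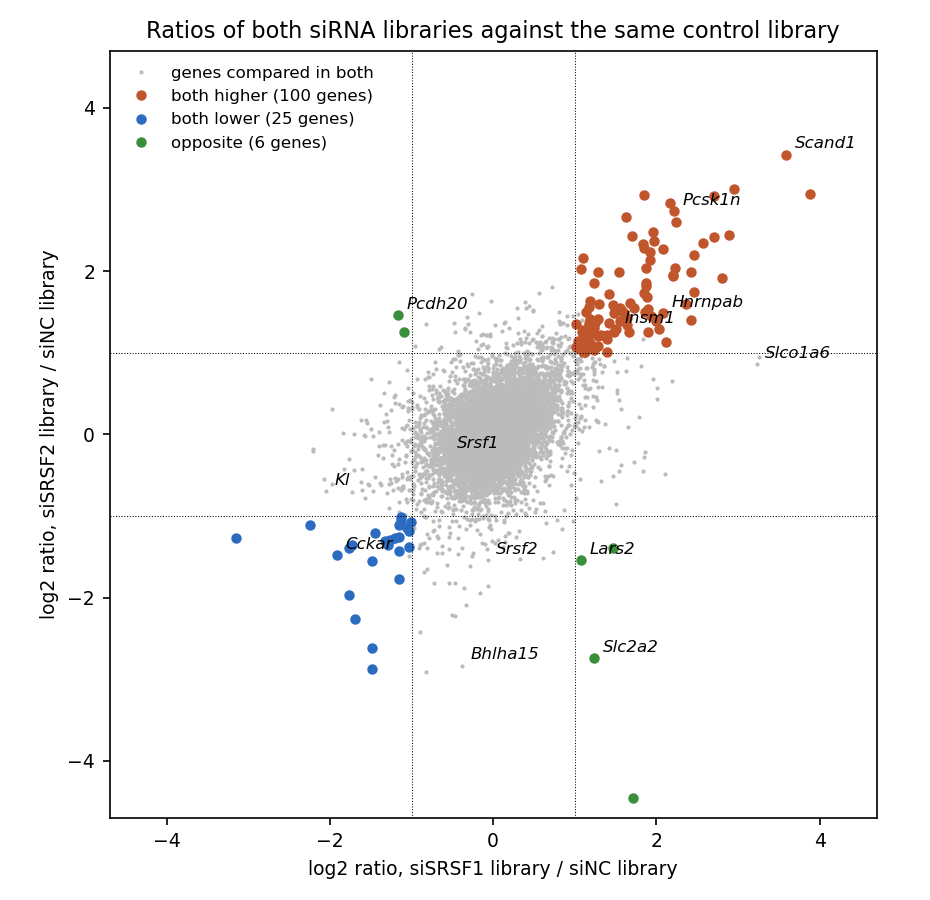
Log2 ratio to siNC of each compared gene in the siSRSF1 library (horizontal axis) and the siSRSF2 library (vertical axis), with genes called higher in both (100), lower in both (25) or in opposite directions (6) marked by colour. Both axes share the siNC library, and the Pearson r across genes is 0.471.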

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

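All values from GC correction, length correction and totals without the insulin genes were chosen after the data were seen, and the other alternatives were fixed beforehand. With 1 library per group no replicate could be left out, and no paired analysis was possible because each group holds 1 library. Of 729 list medians recomputed under the alternatives, 701 kept their side of the percentile limits, and of 2188 ratios of named genes 2166 kept their call. Direction was checked only for lists that were apart and for genes that were called. The median of a list that was not apart, or the ratio of a gene not called, could change sign and still be counted as kept. The number of lists apart moved by less than 1.5 times in all 27 recomputed values. Plain totals, median-of-ratios factors, totals without insulin genes and a prior of 5 reads moved no count of called genes by 1.5 times or more.

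The counts below are higher and then lower genes, in the order siSRSF1 against siNC, siSRSF2 against siNC and siSRSF1 against siSRSF2. A size rule of 1.5-fold gave 706 and 498, 838 and 499, and 676 and 891, with 283 genes higher and 98 lower in both siRNA libraries. A rule of 3-fold gave 108 and 24, 82 and 23, and 82 and 74, with 34 and 2 shared. These follow from the looser or stricter rule. A minimum of 100 reads, which leaves fewer genes, gave 122 and 35, 129 and 44, and 87 and 108, with 45 and 4 shared. No minimum of reads, which compares more genes, gave 431 and 243 for siSRSF1, 239 lower genes for siSRSF2, 436 higher genes for siSRSF1 against siSRSF2, 46 genes lower in both and a Pearson r of 0.548. FPKM in place of counts, with its own minimum and pseudocount, gave 105 and 12, 95 and 30, and 65 and 36; the cause was not tested.

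GC correction moved the ratio of Srsf1 in siSRSF1 from 0.683 to 0.751, outside its counting interval, and the Pearson r between both siRNA libraries from 0.471 to 0.437. The median of disallowed genes in siSRSF2, -0.19, reversed to 0.03 (0.027) as a 20% trimmed mean; the cause was not tested. The histone median in siSRSF2, -0.21 and not apart, turned to 0.54 both without a minimum of reads and with a minimum of 100 reads, which change the members compared. Depth limits the low end: Cdk6 in siSRSF1, with 20 reads in siNC and 11 in siSRSF1, had an interval of its ratio from 0.209 to 1.06, and genes such as Slc2a2, with 42, 114 and 7 reads, or H1f1, with 1, 23 and 5, rest on few reads.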

Other observations

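The tests in this part were chosen after the results were seen, except those of amino acid and stress genes driven by ATF4 and of 5' TOP mRNAs, which were written before their results were seen, although the value of 1 member, Cebpb, had been seen and it was left out of the ATF4 test afterwards. The extra gene lists used here were written after the fixed lists had been examined.

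Genes of amino acid transport and synthesis that the transcription factor ATF4 drives were higher as a group in the siSRSF2 library. Of 30 compared members, 29 lay above siNC and 5 were called higher, with a median log2 ratio of 0.63. The cystine transporter gene Slc7a11 had 371 reads in siNC and 1375 in siSRSF2, a ratio of 3.11 (2.77 to 3.50). The leucine transporter gene Slc7a5 stood at 2.10 (2.03 to 2.17), which GC correction put at 1.995, below the size rule, Slc7a1 at 1.97, the serine synthesis genes Psph and Phgdh at 1.79 and 1.68, and Pycr1 at 0.853. The 23 compared members in none of the fixed lists, Cebpb left out, had a GC-corrected median of 0.48, at percentile 100 of random lists. In the siSRSF1 library the full list had a median of 0.04 at percentile 76.25, and in siSRSF1 against siSRSF2 it had -0.55 at percentile 0.00. A candidate explanation is that ATF4 activity was higher in the siSRSF2 culture. The list of the unfolded protein and integrated stress response lay below siNC there, with a median of -0.26 at percentile 0.00 and 20 of 32 members below 0. That list is mixed: Manf and Dnajb9 were called lower, while its members shared with the ATF4 list all lay above siNC, from Asns at 1.26 to Atf3 at 2.57. Its median therefore does not decide for or against ATF4. ATF4 protein was not measured, and 1 culture per group leaves a difference in feeding or density open.

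In an extra list of peptide hormone genes, granule genes and a few others, Dlk1 had ratios of 0.534 in siSRSF1 and 0.714 in siSRSF2. Chgb had ratios of 0.649 and 0.787, and Iapp, the amylin gene, of 0.821 and 0.722. Cck, Pcsk1n and Nrtn were called higher in both, although GC correction put Cck at 1.83 and 1.98, below the size rule. Penk and Cartpt were called lower in siSRSF1. Npy stood at 1.74 in siSRSF1 and 0.920 in siSRSF2, and Vgf at 1.62 and 0.865 (GC-corrected 1.21 and 0.658). The members compared in siSRSF2 had a median of -0.25 at percentile 1.15, and those in siSRSF1 had 0.05 at percentile 70.61. In siSRSF1 against siSRSF2 the median was -0.06 at percentile 10.02, which GC correction moved to -0.11 at percentile 2.48, just apart. The list repeats members of the fixed lists, Chgb, Iapp, Vgf and Pcsk1n among them, so its medians are no separate support. Targets of heat shock factor 1 in siSRSF2 had a median of -0.36 over 19 members, 16 of them below 0, at percentile 0.00, against 0.02 at percentile 60.13 in siSRSF1. This list repeats the heat shock genes of the fixed list, Hspa8 and Hspa1b among them, so it is no separate support. In siSRSF2 its other members lay on both sides of siNC, from Cacybp at 0.784 to Dnajb4 at 1.70. No explanation was tested for these values.

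The 100 genes higher in both siRNA libraries were weighed against GC content, the shared control and gene structure. After GC correction 76% of those with a GC value (74 of 98) were still at least 2-fold higher in both, so the GC trend alone does not account for most of them, and counting error in the shared control gave at most 7 shared genes in simulations. An escape of unspliced genes from a common shift concerns only genes with 1 exon, so it is no account of the 83 with more than 1 exon. In siSRSF1 11308 compared genes had more than 1 exon and 281 had 1, so the number 83 was no test of it. For the 15 with 1 exon the escape stays open. After GC correction genes with 1 exon lay higher in the median by only 0.057 in siSRSF2 and 0.106 in siSRSF1. Yet 7.6% against 2.0% and 9.3% against 1.8% were called higher. A difference of the siNC culture or library from both others, beyond counting error, stays open and may be a candidate source, as does a shared response to the loss of either SR protein.

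Replication-dependent histone genes, whose mRNAs end in a stem-loop without a poly(A) tail, were higher in the siSRSF1 library. GC content is argued against, since the GC-corrected median of the list was 1.046. A larger share of cells in S phase stays open: the G1/S median of 0.139 was small but above random lists (percentile 99.11), and how far histone mRNAs would move with it was not measured. The summed reads of 28 histone genes outside the fixed list, with no minimum of reads, were also higher, by 1.476 on the log2 scale (123 reads in siNC and 390 in siSRSF1), but siSRSF2 sums also lay above siNC, with 224 reads outside the list and 3428 against 2018 in it. Polyadenylated histone variants had a median lower by 0.615 than that of the list, as more RNA without a poly(A) tail in that library would give, but were themselves above siNC (0.35, percentile 99.95, and 0.27 at 99.19 in siSRSF2), which it would not give, so it stays open for part of the difference, while reads shared between near-identical copies were not tested.

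Cholesterol, heat shock and G2/M genes were lower together in the siSRSF2 library. Of these lists, the median nearest 0 was -0.356 after GC correction, -0.363 after length correction and -0.286 with the insulin genes left out of the totals. The GC trend does not account for the pattern, but correction for it could hardly have ended it. The lists had a median GC content of 50.2%, 49.2% and 47.3%, against 49.9% for all compared genes. Even the tenth of genes with the lowest GC content had a median log2 ratio of only -0.05 in siSRSF2. The other 2 settings could hardly have ended the pattern either. The ratios had almost no trend with transcript length (Spearman rho -0.011). Totals without the insulin genes, which also leave out TMM scaling, shift all genes alike, and moved the median of all compared genes only from 0.020 to 0.078. G1/S genes were not lower with the G2/M genes, with a median of 0.07 at percentile 93.97. No biological explanation was tested, and a difference in density, serum or handling between single cultures could give the same pattern and stays open.

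Ribosomal protein genes were lower in both siRNA libraries. Whether other mRNAs with a 5' TOP motif, which are translated under the control of mTOR, shared this was not decided. Their GC-corrected percentile was 0.24 in siSRSF2, with a median of -0.28 over 20 members, and 5.65 in siSRSF1, which lies between the limits set in advance. Without GC correction, which was chosen after seeing the data, siSRSF1 had -0.07 at percentile 15.55, so the open outcome depends on that correction. Set against each other, the siRNA libraries had a GC-corrected median of 0.14 for this class at percentile 80.61, which is not apart.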
